A study of Mus musculus with 6 samples.

How the data were processed

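Total RNA from lymph nodes of mice carrying knockouts of Rag2 and of the perforin gene (pfp, current symbol Prf1), and from lymph nodes of wild-type mice, was amplified, biotin-labelled and hybridised to Illumina Mouse Ref-8 v2 BeadChips, per the labels' protocols. The labels define 2 groups of 3 arrays each, with replicates numbered 1 to 3 in both. They do not say whether the replicates came from separate animals, so the p-values measure only the spread between these arrays, which may be technical. Which lymph node was taken, the age and strain of the mice, the chip and the time of collection are not given in the sources used here.

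The deposited table of non-normalized data holds 1 signal intensity per probe and array on a linear scale, exported with GenomeStudio 2011.1 per the submitters' processing notes. The same deposited table holds a detection p-value for each probe and array, which compares the probe with the negative control beads of that array. A second deposited table holds the authors' values on the log2 scale. Its scale was worked out from the values: each of its 6 columns ranked the probes exactly as the intensities of the same array did, and its values differed by at most 0.00078 from a quantile normalization of the log2 intensities with no background correction. All 6 of its columns have a median of 7.38, and no step of centring per probe was seen. The table of the authors' values was used only as an alternative.

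The intensities of all 25697 probes were corrected for background with the normexp model, with the background taken from the detection p-values, then raised by an offset of 16, quantile-normalized and expressed as log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which left 14378 probes and removed 11319. Each probe was fitted with lmFit and eBayes, two-sided, as knockout minus wild type, and p-values were adjusted by Benjamini-Hochberg over all probes tested. An adjusted p under 0.05 was called. All fold changes below are on this normalized log2 scale, where the offset shrinks the change of dim probes. Where a probe was not above background on any array of 1 group, the fold is given as a lower bound. For it, the dim group's level is the mean over its arrays of the higher of the probe's own signal and the lowest signal among detected probes.

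Gene names come from the platform annotation, in which 23978 probes have 1 symbol, 0 have several and 1719 have none. A RefSeq gene table of assembly GCF_000001635.26 (GRCm38.p6) matched 23962 probes by Entrez identifier and changed 0 symbols. The files name no genome build, so no coordinates are given, and that table served only for names and for the order of neighbouring genes. A gene was represented by the detected probe with the highest mean over the 6 arrays, which gave 9973 genes.

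Before the data were examined, 32 gene lists were fixed from textbook knowledge of lymph node cell types, of tissues that a dissection can carry along and of processes such as cell division, the clock and the heat shock response. Of their 669 entries, 597 were on the array and 477 were tested. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with a correlation estimated from the data was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The genes named in the text follow a rule that was also fixed beforehand. It takes Rag2 and Prf1, and the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, no overlap between the groups and detection on all 3 arrays of the higher group. From each list it takes up to 3 called members in the direction most called members took and 1 in the other direction. Genes named outside this rule are marked as chosen after their values were seen, and so were Jchain, Xrcc6, Prkdc, Cd14, Fmod, Pdgfrb, Il16, Lta, Egr2, Jun, Tnni2, Dbp, Per2, Per3, Cry2 and the list members given as not called, which complete small counts.

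The test was tried on simulated data with the measured mean and spread of each of the 14378 probes, 3 arrays against 3, in which 200 probes were changed. It recovered 70% of the 50 probes lowered by 2 on the log2 scale and 66% of the 50 raised by 2. At a change of 1 it recovered 18% of the lowered and 24% of the raised probes, and it called 3 of 14178 unchanged probes. In the measured data 4119 probes were called, so the adjustment was less strict there than with 200 changed probes. These shares thus do not give the recovery or the false calls of the measured test. In a simulation of the lists with 1 list raised by 1, camera called that list and 0 of the 30 others. The simulated genes were independent of each other, which the measured ones were not. How often camera calls an unchanged list in the measured data is thus not shown.

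The number of arrays limits the precision of every comparison. Between 13185 and 14468 probes were detected per array. The median intensity of probes detected on no array was 87.9 to 91.9 on the knockout arrays and 130 to 147 on the wild-type arrays. The files name no chip or scan, so a chip effect on the groups was not tested, and the block on slide or scan was not run. The alternatives covered the background correction, offset and scaling, the authors' values, the filter on dim probes, the variance model, array weights, the replicate number as a block, the threshold, the probe used for a gene, the set test and each array left out in turn. After the data were seen, 2 more were added: the mean signal of the exocrine gland list as a covariate, and the knockout arrays against wild-type replicate 2 alone, in which the lone array is assumed to vary as the knockout arrays do. The list mean was 12.28 on wild-type replicate 2, near the knockout arrays, and 6.03 and 6.12 on replicates 1 and 3. The covariate fit thus rests largely on wild-type replicate 2, and the 2 settings are not independent of each other.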

Results

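Gene expression was profiled in lymph nodes of mice lacking Rag2 and perforin and of wild-type mice, with 3 arrays per genotype. RAG2 is part of the recombinase that assembles antigen receptor genes, without which mature B and T cells do not form, and perforin is the pore-forming protein of cytotoxic granules. The series asks how loss of both genes changes the transcriptome of the lymph node. Between 51.3% and 56.3% of the 25697 probes were detected on each array.

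The targeted transcripts themselves gave no check of the genotype. The Rag2 probe was not above background on any of the 6 arrays, with detection p-values of at least 0.332. Of the 2 Prf1 probes, the brighter read 10.87 ± 0.18 (SD, n = 3) in the knockout and 11.01 ± 0.80 (SD, n = 3) in wild type on the log2 scale, a limma log2 fold change of -0.14 (SE 0.40, adjusted p = 0.804). The dimmer read 7.90 ± 0.40 in the knockout and 7.55 ± 0.53 in wild type (log2 fold change 0.35, SE 0.33, limma adjusted p = 0.439), so the probes differed in sign and neither passed the test. Without wild-type replicate 1 the brighter probe's change was 0.31. Where the deletions lie relative to the probes is not given in the sources used here, and a probe outside the deleted part says nothing of the allele.

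B cell transcripts were among the largest falls in the knockout nodes. Fcmr, the IgM Fc receptor, read 14.25 ± 0.26 (SD, n = 3) in wild type and was not above background on any knockout array, at least 349-fold lower. Cd79a, a signalling chain of the B cell receptor, was at least 101-fold lower and Tnfrsf13c, the BAFF receptor, at least 79.7-fold lower. Pou2af1, a B cell transcriptional coactivator, fell by 8.75 (SE 0.43) on the log2 scale, Mzb1, a chaperone of antibody-secreting cells, by 7.10 (SE 0.49), and the follicle-homing receptor Cxcr5 fell by 5.75 (SE 0.31). The T cell receptor chain Cd3d fell by 5.48 (SE 0.33) and the surrogate light chain partner Vpreb3 by 5.23 (SE 0.38). Slpi, a secreted protease inhibitor, fell by 6.37 (SE 0.25) from 15.55 ± 0.44 to 9.17 ± 0.16, and the calcium channel gene Cacna1h by 5.73 (SE 0.55). The limma adjusted p of these 10 genes lay between 0.00012 for Fcmr and 0.0025 for Cacna1h, and each stayed under 0.05 with any 1 array left out.

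Among the largest rises, Tmem87a read 10.33 ± 0.43 (SD, n = 3) in the knockout and was not above background in wild type, at least 26.8-fold higher (limma adjusted p = 0.00039). Klrb1b, an inhibitory lectin-like receptor of natural killer and dendritic cells, rose 12.9-fold, Tmem45b 12.0-fold, Bcl2l14 10.5-fold, Plac9a 8.56-fold and the interleukin 25 receptor Il17rb 8.41-fold, with limma adjusted p from 0.0017 for Plac9a to 0.0074 for Bcl2l14. For Bcl2l14, and for Wnt4 given next, 1 of 2 probes passed the test. The other 4 of the 10 largest rises were 2310057J18Rik (log2 fold change 7.51, SE 1.69), the kallikreins Klk1b26 (7.18, SE 1.93) and Klk1b22 (6.67, SE 1.89), and the secreted signalling protein Wnt4 (3.06, SE 0.89), with limma adjusted p of 0.022, 0.037, 0.043 and 0.045. These 4 genes were also detected on wild-type replicate 2 and on neither other wild-type array, and their calls were lost without knockout replicate 2 or 3 or without wild-type replicate 1 or 3, where the adjusted p reached 0.074, 0.116, 0.124 and 0.129. With the mean signal of the exocrine gland list as a covariate, the log2 fold changes of these 4 genes were 2.98, 3.28, 4.31 and 1.43. Their limma adjusted p were then 0.046, 0.294, 0.274 and 0.354. Of the list's 10 members, 4 read near the top of the scale on wild-type replicate 2 and each knockout array. The covariate thus follows differences among those arrays only in part. Against wild-type replicate 2 alone the log2 fold changes were 3.71, 4.28, 5.32 and 1.90. Klk1b genes are near-identical copies that a probe may not separate.

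**Figure D1:**
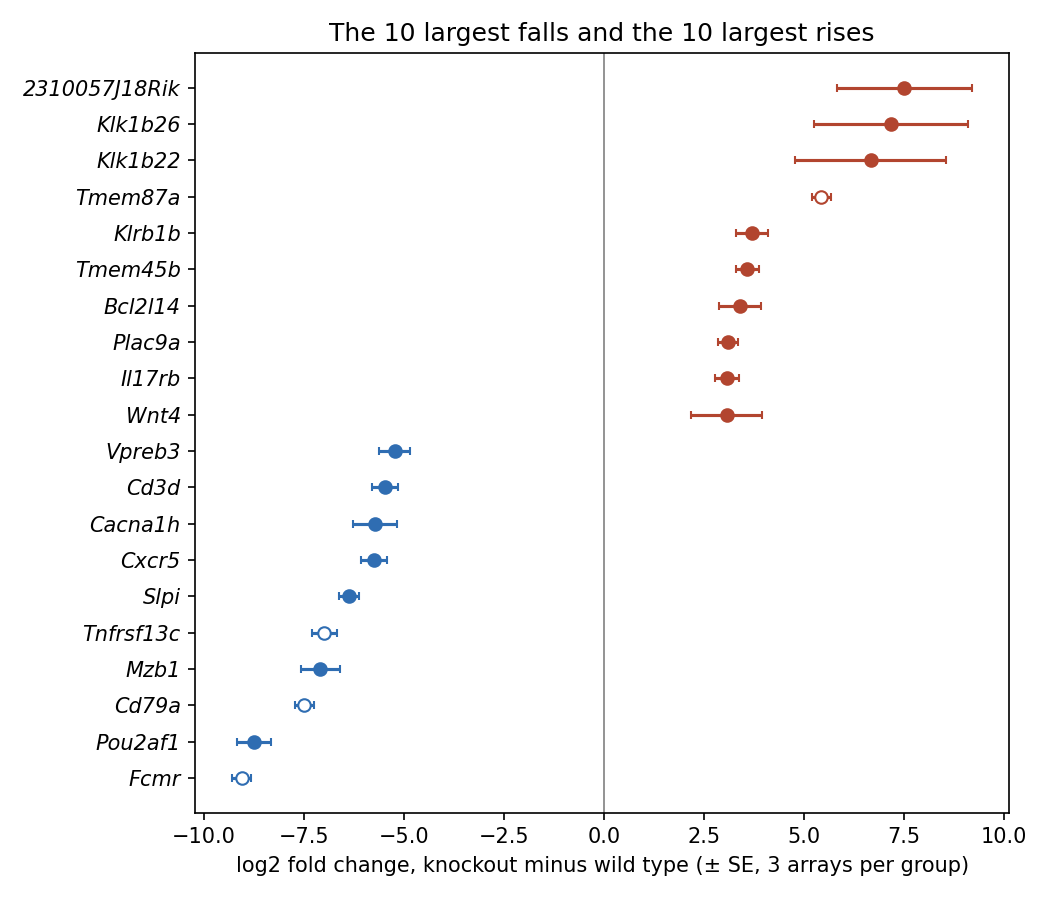
The log2 fold change (knockout minus wild type, x axis) of the 10 genes with the largest falls (blue) and the 10 with the largest rises (red), with the limma standard error as bars over 3 arrays per group; open circles mark genes not above background on any array of 1 group. Fcmr, Pou2af1 and Cd79a lie farthest to the left, and the error bars of 2310057J18Rik, Klk1b26 and Klk1b22 are the widest.

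In all, limma called 4119 of 14378 probes, 1455 higher and 2664 lower in the knockout, of which 721 and 1671 changed at least 2-fold. At the level of genes, 1018 rose and 1724 fell among 9973. The groups did not overlap for 48.2% of the tested probes, where chance gives 10% on average. Probes vary together, so a single split of the arrays can lie far from that average. A chip effect on the groups was not tested. The number of called probes was 2393, 1991 and 1805 without knockout replicates 1, 2 and 3, and 2310, 6298 and 2101 without wild-type replicates 1, 2 and 3. It was 2582 with the mean signal of the exocrine gland list as a covariate and 950 against wild-type replicate 2 alone, both chosen after the data were seen. Of 99 named genes, 66 kept their call with this covariate and 43 against wild-type replicate 2 alone. The calls lost with the covariate were those of Klk1b26, Klk1b22, Wnt4, Gzmm, Eomes, Id2, Cd163, Timd4, Cxcr2, Mcpt4, Ch25h, Vwf, Glycam1, Lmod1, Mylk, Scd1, Mybpc2, Mylpf, Alas2, Fech, Cnp, H2-Aa, H2-Ab1, Ddx58, Cd55, Cdca8, Hmgb2, Tdp1, Nhej1, Ier3, Atf3, Nr1d1 and Nfil3. Some of these kept about the same log2 fold change: Id2 went from -0.73 to -0.74 and Scd1 from -0.73 to -0.78. Fech went from -0.69 to -0.80 and Cd163 from 1.67 to 1.60. Others shrank, such as Wnt4 (3.06 to 1.43), Gzmm (-1.67 to -0.74) and Lmod1 (1.56 to 0.44). A lost call with a kept change does not speak for gland tissue.

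B and T cell markers fell almost as a whole. Of 21 B cell markers, 20 fell and 0 rose (21 and 0 adjusted over the list alone), with a median log2 fold change of -3.70, or -3.22 with the 6 members that were below background in the knockout at their bound. Spib alone missed the threshold, at -1.02 (adjusted p = 0.085). The list was called lower by camera (adjusted p = 2.1e-16, and adjusted p = 0.788 with an estimated correlation). The adjustment gave 0.788 to several lists alike, so it does not rank them. Their unadjusted camera p with an estimated correlation ran from 0.067 for this list to 0.229 for the V(D)J recombination list. Of 25 T cell markers, 22 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -2.65, or -2.61 at the bounds. Cd3e, a chain of the T cell receptor complex, fell by 5.13 (SE 0.45) and Cd6 fell by 5.11 (SE 0.36), whereas Il7r read -0.62, Cd4 -0.43 and Icos -1.11, all with adjusted p over 0.05. Camera called this list lower as well (adjusted p = 1.4e-14; adjusted p = 0.788 with an estimated correlation).

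Among 11 plasma cell and germinal centre markers, 4 fell and 0 rose (4 and 0 adjusted over the list alone). Besides Mzb1 these were Tnfrsf17, the BCMA receptor of plasma cells, which was not above background in the knockout and was at least 8.0-fold lower, Gcsam, which fell by 2.09 (SE 0.31), and the joining chain of polymeric antibodies, Jchain, which fell by 2.04. The camera call on that list had an adjusted p of 0.0041, and an adjusted p of 0.788 with an estimated correlation. The number of members that fell was 6 without wild-type replicate 2 and 4 without any other array.

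Genes of cell division were lower in the knockout, though how many passed the test hung on single arrays. Of 24 cell cycle genes, 23 fell and 0 rose (23 and 0 adjusted over the list alone), with a median log2 fold change of -1.84, or -1.70 with 2 members at their bound. The spindle protein gene Nusap1 fell by 3.17 (SE 0.36) and Cdc20, an activator of the anaphase-promoting complex, fell by 2.49 (SE 0.38), and both kept their calls with any 1 array left out; Bub1b missed the threshold at -0.64. The number that fell was 7 without knockout replicate 2, 7 without knockout replicate 3, 10 without wild-type replicate 1 and 7 without wild-type replicate 3. It was 8 with the gland covariate and 1 against wild-type replicate 2 alone, whose list mean of 9.76 lay between those of the knockout (8.42 to 9.05) and the other wild-type arrays (10.90 and 10.78). Camera called the list lower (adjusted p = 3.4e-09; adjusted p = 0.788 with an estimated correlation).

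Of 8 V(D)J recombination and end-joining genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone). Xrcc4, a scaffold of the ligase that joins broken ends, fell by 1.14 (SE 0.15, limma adjusted p = 0.0047) and was called with any 1 array left out. The other falls were Hmgb2, Tdp1, Xrcc6 and Prkdc, and Nhej1 rose by 0.52 (SE 0.14); without knockout replicates 1, 2 or 3 or wild-type replicates 1 or 3 the falls numbered 2, 1, 1, 1 and 1, and 0 genes rose with any 1 array left out. The camera adjusted p of 0.0495 for this list was an adjusted p of 0.788 with an estimated correlation, 0.072, 0.053 and 0.065 without knockout replicates 1, 2 and 3, and 0.062 and 0.077 without wild-type replicates 1 and 2. The camera adjusted p was 0.056 with the replicate number as a block and 0.141 with the gland covariate. The mean change of the list was -0.66 on all arrays and -0.45 against wild-type replicate 2 alone.

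Several dendritic cell genes were higher in the knockout. The RNA came from whole nodes, where a lower share of lymphocytes would raise other transcripts. A change of a gene here or below may thus reflect the mix of cells, which was not tested. Of 16 dendritic cell markers, 8 rose and 0 fell (8 and 0 adjusted over the list alone). Ccl17, a chemokine that attracts CCR4-bearing T cells, rose 7.48-fold and the actin-bundling protein Fscn1 3.55-fold, while Xcr1 (-0.26), Siglech (-0.07) and Cd209a (0.23) did not pass the test. The number that rose was 5 without knockout replicate 2 or wild-type replicate 1. Camera called the list higher (adjusted p = 0.020; adjusted p = 0.822 with an estimated correlation), but not without knockout replicate 1 (0.072) or wild-type replicate 2 (0.172).

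Of 24 macrophage and monocyte markers, 4 rose and 1 fell (3 and 1 adjusted over the list alone). Timd4, a receptor for phosphatidylserine on resident macrophages, fell by 1.36 (SE 0.23, limma adjusted p = 0.0095). Its log2 fold change was -1.15 with the gland covariate (limma adjusted p = 0.056) and -1.14 against wild-type replicate 2 alone. C1qa, a chain of complement component C1q, rose 3.77-fold, the haptoglobin-haemoglobin receptor Cd163 3.19-fold, the scavenger receptor Marco 2.31-fold and the lipopolysaccharide co-receptor Cd14 by 1.20 on the log2 scale, with limma adjusted p from 0.017 for C1qa to 0.042 for Marco. All 4 rises were lost without any 1 knockout array or without wild-type replicate 1, where C1qa reached an adjusted p of 0.059 and Marco 0.122, and 8 markers rose without wild-type replicate 3 and 3 fell without wild-type replicate 2. Camera called the list higher (adjusted p = 0.041; adjusted p = 0.867 with an estimated correlation), but not without knockout replicate 1 (0.082) or wild-type replicate 1 (0.051) or 2 (0.273). With the gland covariate 13 macrophage markers were higher and 0 lower.

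The called natural killer and cytotoxic lymphocyte markers went both ways, while the list had a median log2 fold change of 0.82 (quartiles -0.07 and 1.18). Of 17 tested, 1 rose and 2 fell (1 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.175). Klrb1c, the NK1.1 antigen, rose 4.16-fold (limma adjusted p = 0.018), a call lost without any 1 knockout array or wild-type replicate 1, where the adjusted p reached 0.061. The granzyme Gzmm fell by 1.67 (SE 0.39) and the transcription factor Eomes by at least 1.36-fold, both called only in the full set and without wild-type replicate 2 (adjusted p of up to 0.088 and 0.133 with another array left out); without that array 2 markers rose. With the gland covariate 10 of these markers were higher and 0 lower, and the list was called (camera adjusted p = 0.00033).

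Among 11 innate lymphoid markers 1 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.794). The inhibitory receptor Klrg1 rose 3.77-fold but not without knockout replicate 2 or wild-type replicate 3 (adjusted p up to 0.065), and Id2, with 1 of 2 probes past the test, fell by 0.73 (SE 0.22), lost without any 1 array (up to 0.142); 2 rose without wild-type replicate 1 and 3 without wild-type replicate 2. Among 9 markers of mast cells, basophils and eosinophils 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.208). These were the mast cell protease Mcpt4 (2.54-fold), called only with all arrays and without wild-type replicate 2 (up to 0.107), and the transcription factor Gata2 (1.94-fold), lost without any 1 knockout array or wild-type replicate 3 (up to 0.101).

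Stromal genes moved in both directions. Of 21 lymph node stromal markers, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.758). The B cell-attracting chemokine Cxcl13 fell by 2.04 (SE 0.35) and Bst1 by at least 2.35-fold, while Ltbr, the lymphotoxin beta receptor, rose 2.89-fold, all 3 with any 1 array left out. Ch25h, which makes an oxysterol that guides B cells, fell by 1.46 (SE 0.37), called only with all arrays and without wild-type replicate 2 (up to 0.101). Fmod (0.88) and Pdgfrb (1.31) also rose on the log2 scale, but 1 marker in all rose without knockout replicate 1 or 3. Of 9 high endothelial venule genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.883). Glycam1, a mucin ligand for L-selectin, fell by 1.95 (SE 0.32, limma adjusted p = 0.0089). Its log2 fold change was -1.58 with the gland covariate (limma adjusted p = 0.054) and -1.72 against wild-type replicate 2 alone. Lifr rose 2.29-fold, with 1 of its 3 probes past the test. Without wild-type replicate 2, 2 of the high endothelial venule genes rose and 2 fell. With the gland covariate 6 stromal markers were higher and 2 lower, and that list was called (camera adjusted p = 0.0089).

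Of 25 fibroblast and matrix genes, 4 rose and 0 fell (3 and 0 adjusted over the list alone), among them the collagen Col14a1 (4.03-fold), the microfibril protein Mfap4 (3.95-fold) and the lysyl oxidase Loxl1 (2.78-fold, lost without knockout replicate 3 or wild-type replicate 1, up to 0.066). Camera called that list higher (adjusted p = 0.0032; adjusted p = 0.822 with an estimated correlation), though not without wild-type replicate 2 (0.055), and 2 genes rose without knockout replicate 3 or wild-type replicate 1, and 11 with the gland covariate. Of 20 adipocyte markers, 6 rose and 1 fell (9 and 1 adjusted over the list alone). The glycerol phosphate dehydrogenase Gpd1 rose 3.80-fold, the lipid droplet protein Cidec 2.70-fold and the hormone-sensitive lipase Lipe 2.01-fold. The desaturase Scd1 fell by 0.73 (SE 0.20), a call lost without knockout replicate 2 or 3 or wild-type replicate 1 or 3 (up to 0.127). The number of adipocyte genes that rose was 3 without any 1 knockout array or wild-type replicate 1, and 2 fell without knockout replicate 1. The list was called higher by camera (adjusted p = 0.0032; adjusted p = 0.788 with an estimated correlation).

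Of 20 blood endothelial markers, 2 rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.021 and adjusted p = 0.822 with an estimated correlation. The von Willebrand factor gene Vwf rose 3.64-fold and endoglin, Eng, 2.34-fold; both calls were lost without any 1 knockout array or wild-type replicate 1, and that of Vwf without wild-type replicate 3 (adjusted p up to 0.128 and 0.101). The log2 fold change of Vwf went from 1.86 to 0.66 with the gland covariate (adjusted p = 0.362), and it was 0.76 (0.337) against wild-type replicate 2 alone, whereas that of Eng went from 1.23 to 2.02 (0.010). The list call was lost without knockout replicate 1 (0.072) or wild-type replicate 2 (0.166), and with the gland covariate 11 markers were higher; 4 rose and 1 fell without wild-type replicate 2. Of 14 smooth muscle and pericyte markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.029, adjusted p = 0.788 with an estimated correlation, and 0.072 without knockout replicate 1. The actin-binding protein Tagln rose 3.59-fold (lost without knockout replicate 2 or 3 or wild-type replicate 3, up to 0.058), Lmod1 2.95-fold and Mylk 1.46-fold, the latter both lost without any array but wild-type replicate 2 (up to 0.12); without that array 7 rose. The covariate took the log2 fold change of Lmod1 from 1.56 to 0.44 (adjusted p = 0.293), that of Mylk from 0.55 to 0.35 (0.262) and that of Tagln from 1.85 to 0.93 (0.046). Of 10 lymphatic endothelial markers, 2 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.231, and 0.036 without wild-type replicate 3). These were the scavenger receptor Stab2 (2.62-fold) and the integrin Itga2b (2.32-fold), lost without any 1 knockout array or wild-type replicate 1 (up to 0.108 and 0.119). The lymphatic list was called with the gland covariate (camera adjusted p = 0.00015; 5 markers higher and 0 lower).

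**Figure D2:**
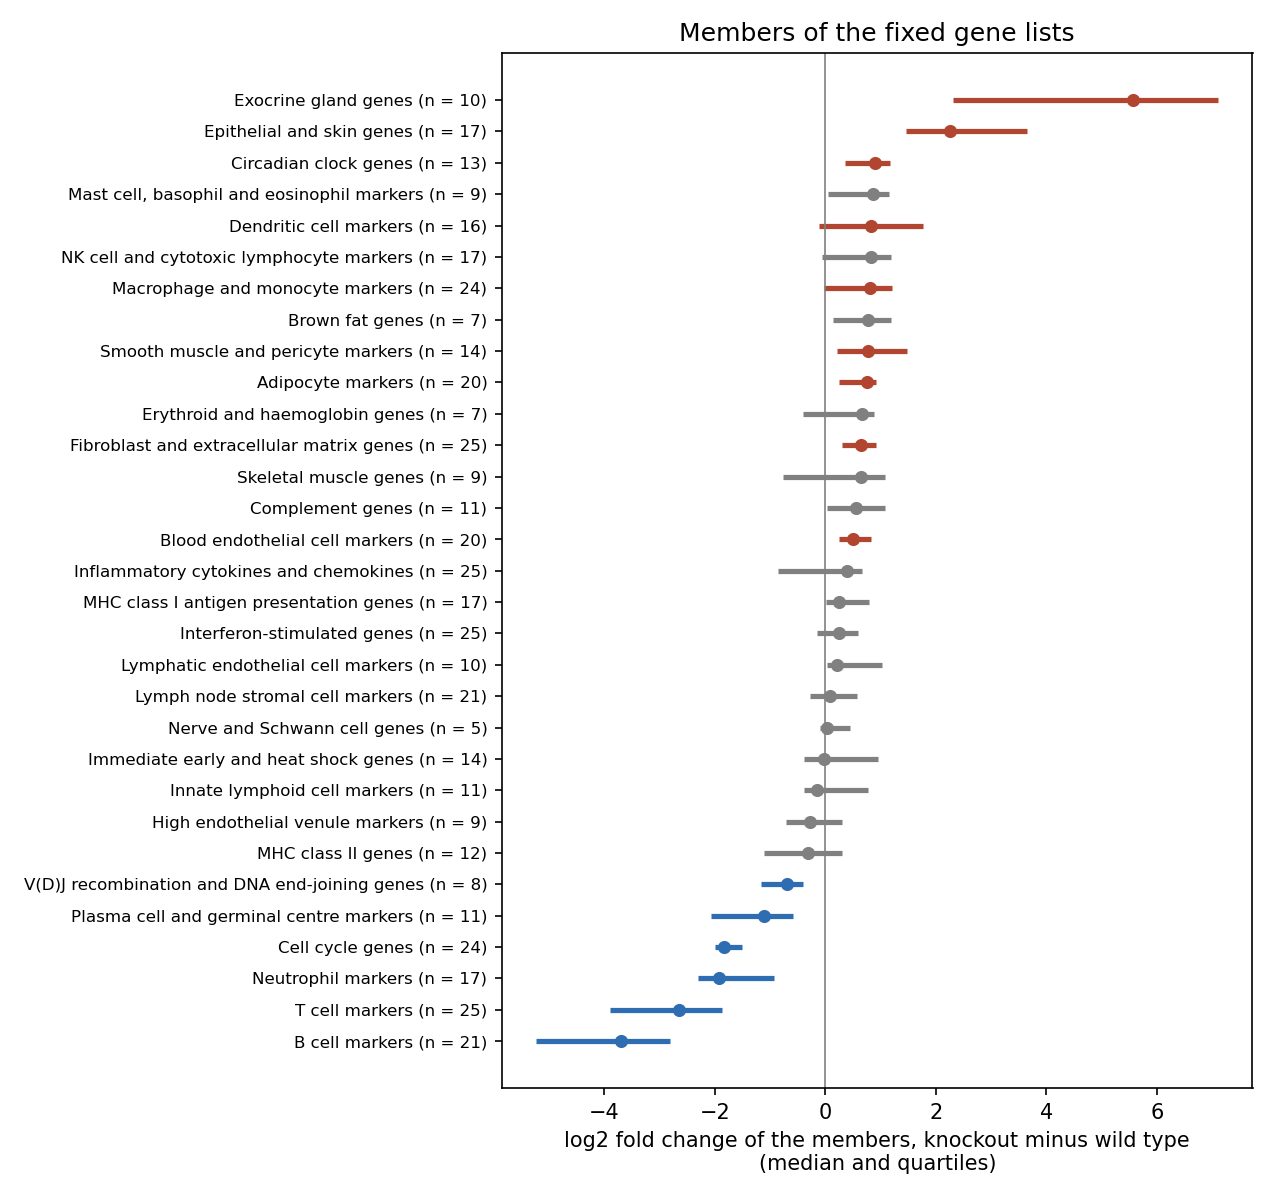
Median (point) and quartiles (bar) of the log2 fold change (knockout minus wild type, x axis) of the tested members of each list with at least 5 of them (y axis, n = members); red lists were called higher and blue lists lower by camera with a preset correlation, and grey lists were not called. The B cell and T cell lists have the lowest medians, -3.70 and -2.65, and the exocrine gland list the highest, 5.56.

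Antigen presentation genes divided by gene. Of 12 MHC class II genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.366). H2-DMb2 fell by 2.57 (SE 0.39) and H2-Eb2 fell by 2.17 (SE 0.23). H2-Aa fell by 0.68 (SE 0.19), called only with all arrays and without wild-type replicate 2 (up to 0.132), and H2-Ab1 rose 1.74-fold with 2 of its 4 probes past the test, lost without any 1 knockout array or wild-type replicate 3 (up to 0.112). H2-Ab1 read at least 15.74 on the knockout arrays, near the highest signal of 16.04, where differences are compressed. Of 17 MHC class I genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.202, and 0.037 without knockout replicate 2). H2-Q1 was at least 2.51-fold higher in the knockout, and H2-K1 rose 1.86-fold, lost without any 1 array (up to 0.114). Without wild-type replicate 2, 5 class II genes fell. The class I list was called with the gland covariate (camera adjusted p = 0.0032; 5 genes higher and 0 lower). Close paralogs among the H2 genes may not be separated by a probe.

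Inflammatory genes also went both ways. Of 25 cytokines and chemokines, 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.758). Il12a, a subunit of interleukin 12, fell by 2.46 (SE 0.32), and Il16 and the lymphotoxin gene Lta fell by 2.44 and 2.20. Interferon gamma, Ifng, rose 3.41-fold and the chemokines Ccl6 3.38-fold and Ccl9 2.79-fold, calls lost without any 1 knockout array or wild-type replicate 1, and for Ifng and Ccl6 wild-type replicate 3 (up to 0.076, 0.110 and 0.115); 0 members rose without knockout replicate 2 or 3 or wild-type replicate 1, 1 without knockout replicate 1 and 2 without wild-type replicate 3. The falls numbered 5 without knockout replicate 1 and 6 without wild-type replicate 2. Of 25 interferon-stimulated genes 1 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.534). Trim30a fell by 1.71 and the RNA sensor Ddx58 fell by 1.54, both lost without knockout replicate 2 or 3 or wild-type replicate 3 and Ddx58 also without wild-type replicate 1 (up to 0.054 and 0.058), and the CXCR3 ligand Cxcl9 rose 3.16-fold, lost without knockout replicate 1 or 3 or wild-type replicate 1 (up to 0.105). Without wild-type replicate 2, 2 interferon-stimulated genes rose and 5 fell. Of 11 complement genes 2 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.242). C6 rose 3.34-fold and C4b 3.03-fold, lost without any 1 knockout array or wild-type replicate 1 (up to 0.066 and 0.072), and the complement regulator Cd55 fell by 1.15 (SE 0.29), lost without knockout replicate 1 or 2 or wild-type replicate 1 or 3 (up to 0.093); 3 fell without wild-type replicate 2. All 3 of these lists were called higher with the gland covariate. Among cytokines and chemokines 6 were higher and 3 lower (camera adjusted p = 0.024). Among interferon-stimulated genes 8 were higher and 1 lower (0.0032), and among complement genes 5 were higher and 0 lower (0.0092). These covariate calls rest largely on wild-type replicate 2, the wild-type array with a gland signal near the knockout level.

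The mean signals of the salivary gland and epithelial lists were higher on all 3 knockout arrays and on wild-type replicate 2 than on the other 2 wild-type arrays, though not those of every member. Dcpp1 and Bpifa2, secreted salivary proteins chosen here after their values were seen, read 15.93 and 16 on wild-type replicate 2, at least 15.79 and 15.82 on the knockout arrays, and 5.09 and 5.52 on wild-type replicate 1. By contrast, the keratin Krt10, also chosen after its values were seen, read 9.14 and 8.74 on wild-type replicates 1 and 3 and 9.0 to 9.64 on the knockout arrays. The mean of the 10 exocrine gland genes was 12.21, 13.46 and 12.87 on the knockout arrays and 6.03, 12.28 and 6.12 on wild-type replicates 1, 2 and 3; 1 gene rose and 0 fell (0 and 0 adjusted over the list alone). That gene was the elastase Cela1 (3.19-fold, limma adjusted p = 0.046), lost without any 1 knockout array or wild-type replicate 1 (up to 0.124). Of 17 epithelial genes 0 rose and 0 fell (0 and 0 adjusted over the list alone); their means were 8.33, 9.94 and 9.29 in the knockout and 5.64, 8.94 and 5.90 in wild type. Camera called the 2 lists higher, with adjusted p = 0.024 and 0.014, and adjusted p = 0.788 and 0.822 with an estimated correlation. Their mean changes were 4.71 and 2.36 on all arrays, but 0.57 and 0.25 against wild-type replicate 2 alone. With the gland covariate the epithelial mean change was -0.16. Without wild-type replicate 2, 7 exocrine genes rose, and 11 epithelial genes rose and 1 fell; 2 epithelial genes rose without knockout replicate 1. The exocrine call was lost without knockout replicate 2 (0.059) or wild-type replicate 1 (0.062) and the epithelial call without wild-type replicate 1 (0.051).

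**Figure D3:**
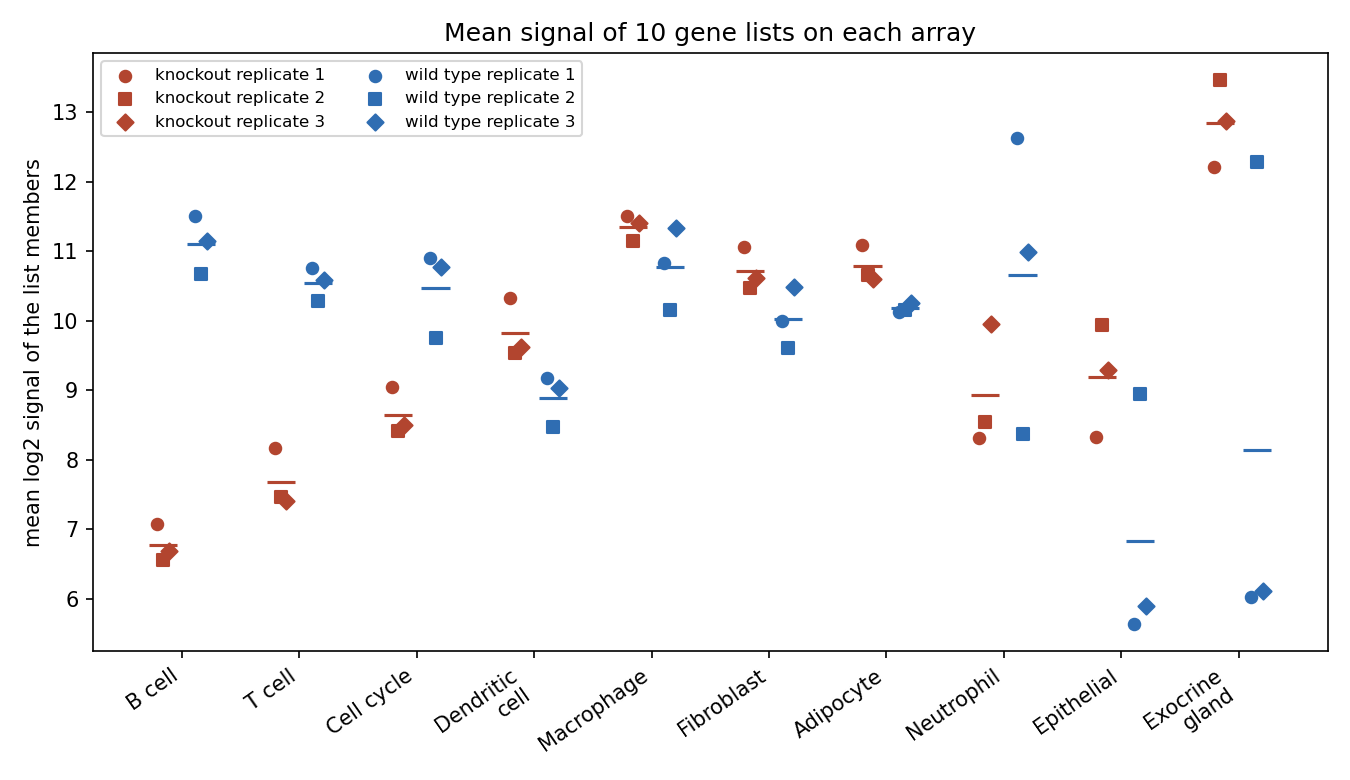
Mean log2 signal (y axis) of the tested members of 10 gene lists (x axis) on each array; red symbols are knockout arrays, blue symbols wild-type arrays, the symbol shape gives the replicate number, and short lines are group means. Wild-type replicate 2 (blue squares) lies with the other wild-type arrays for the B cell and T cell lists, and at 12.28 near the knockout arrays for the exocrine gland list.

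Of 13 circadian clock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Arntl, which encodes the activator BMAL1, fell by 1.75 (SE 0.18, limma adjusted p = 0.0029), and the D-box activator Tef rose 3.77-fold (limma adjusted p = 0.0034). Arntl and Tef kept their calls with any 1 array left out, whereas 1 clock gene in all rose without knockout replicate 2 or 3 or wild-type replicate 1 or 3, and 3 without knockout replicate 1. Camera called the clock list higher (adjusted p = 0.041; adjusted p = 0.788 with an estimated correlation), but not without knockout replicate 2 (0.053) or wild-type replicate 1 (0.062) or 3 (0.060), nor with the gland covariate (0.437) or against wild-type replicate 2 alone (0.229). Of 14 immediate early and heat shock genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.668). The inducible chaperone Hspa1a rose 3.93-fold, and the early growth response factor Egr1 fell by 2.11 (SE 0.29). The other calls were falls of Egr2 (-1.90) and rises of Ier3 (3.73-fold), Atf3 (2.15-fold) and Jun (0.98 on the log2 scale); Ier3 was lost without wild-type replicate 1 or 3 (up to 0.063), and Atf3 also without knockout replicate 1 or 2 (up to 0.104), and the number that rose was 2 without knockout replicate 1 or 2 or wild-type replicate 1 and 1 without wild-type replicate 3.

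The remaining lists gave few calls. Skeletal muscle genes (9 tested) held 2 that rose and 2 that fell, erythroid genes (7 tested) 2 and 1, nerve and Schwann cell genes (5 tested) 0 and 1, and brown fat genes (7 tested) 0 and 0. Adjusted over the list alone these were 2 and 2, 4 and 1, 0 and 1, and 0 and 0, and camera gave adjusted p = 0.485, 0.293, 0.913 and 0.384. The muscle enolase Eno3 rose 2.76-fold and the erythroid tetraspanin Tspan33 2.28-fold. The other calls were Tnni2 (1.11) and Mylpf (-0.92) of muscle, Alas2 (0.97) and Fech (-0.69, 1 of 2 probes) of erythroid cells and the myelin enzyme gene Cnp (-1.08), with log2 fold changes in brackets, and Mybpc2 of muscle, not above background in the knockout and at least 1.26-fold lower. Of these, Mybpc2 was lost without knockout replicate 2 or 3 (up to 0.057), Alas2 and Cnp without knockout replicate 2 or 3 or wild-type replicate 1 or 3 (up to 0.103 and 0.112), Mylpf without any array but wild-type replicate 2 and Fech without any array but knockout replicate 3 (both up to 0.12). Among muscle genes 1 rose without any 1 knockout array or wild-type replicate 3, and among brown fat genes 3 rose without wild-type replicate 2. Of 3 sex-linked genes, too few for the list test, 2 fell (2 adjusted over the list alone): the Y-linked demethylase Kdm5d by 1.97 (SE 0.21) and Eif2s3y by 1.46 (SE 0.32), the latter with an adjusted p of up to 0.071 when knockout replicate 1 or 2 or wild-type replicate 3 was left out. The third, Uty, did not pass the test (log2 fold change -0.19, limma adjusted p = 0.352). All 3 were detected on every knockout and every wild-type array. Whether the sex of the mice differed between the groups was not tested. The mean and the median differed in sign for the innate lymphoid (0.26 and -0.15), nerve (-0.012 and 0.036), cytokine (-0.027 and 0.38) and immediate early lists (0.14 and -0.027).

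Array correlations placed wild-type replicate 2 between the groups. Pearson's r across the tested probes was 0.960 to 0.980 among the knockout arrays and 0.984 between wild-type replicates 1 and 3. Wild-type replicate 2 correlated at 0.884 and 0.893 with the other wild-type arrays and at 0.915 to 0.930 with the knockout arrays. The first principal component, with 71.7% of the variance, placed it at -5.37, between the knockout arrays (-74.85 to -39.80) and wild-type replicates 1 (96.11) and 3 (89.65). On the second, with 16.7%, it lay at -71.49 and the other 5 arrays between 6.07 and 35.20.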

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

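The gland covariate and the comparison with wild-type replicate 2 alone were chosen after seeing the data. Against 4119 called probes (1455 higher, 2664 lower, 2392 at least 2-fold), array weights gave 7968 (3633 higher, 4335 lower, 3834 at least 2-fold), an adjusted p under 0.01 gave 1302 (297, 1005, 1197), a required 2-fold change 2392 (721, 1671), and 1 probe per gene 2670 (1695 lower, 1552 at least 2-fold), where fewer features were counted. The gland covariate gave 2582 (1367 lower), and wild-type replicate 2 alone 950 (365, 585), all 950 at least 2-fold. Without background correction 1302 called probes changed at least 2-fold, and 1310 with the authors' values. With 1 array left out the total ranged from 1805 to 6298, higher from 482 to 2802, lower from 1323 to 3496 and 2-fold changes from 1598 to 3856; for array weights and left-out arrays the cause was not tested, apart from the smaller number of arrays.

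Of the lists, 15 were called (9 higher, 6 lower). Splits of the arrays that mix the genotypes called between 8 and 17 lists. Each of these splits still carries part of the genotype difference, so they do not show how many lists chance alone would call. Detection on all 6 arrays gave 8 (5, 3), array weights 9 (4 higher), an estimated correlation 0 (0, 0) and fry 4 (0 higher, 4 lower), where fry asks another question. The lists that fry called were those of B cells (fry adjusted p = 0.0028), T cells (0.0051), plasma cells and V(D)J recombination (both 0.036). With 1 array left out the number ranged from 9 to 14, with 5 to 9 higher and 4 to 5 lower. The change of the brighter Prf1 probe ranged from -0.46 to 0.31 with 1 array left out; it was 0.61 with the gland covariate and 0.49 against wild-type replicate 2 alone, and no setting brought an adjusted p under 0.05. The mean correlation of wild-type replicate 2 with the knockout arrays minus that with the other wild-type arrays was 0.032, and it was 0.013 with no filter, 0.042 with a detection p under 0.01, and -0.0020 with detection on all 6 arrays. That filter removes the probes silent in 1 group.

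For list means that changed sign the cause was not tested. Inflammatory cytokines (-0.027) read 0.0040 with the authors' values, 0.0043 without background correction, 0.00085 with the 75th percentile, 0.033 with cyclic loess, 0.0012 as the mean of probes, 0.68 with the gland covariate and 0.52 against wild-type replicate 2 alone. Nerve genes (-0.012) read 0.017, 0.051 and 0.022 with median, 75th percentile and cyclic loess scaling, 0.049 with array weights and 0.098 as the mean of probes. Stromal markers (0.0060) read -0.28 with array weights and -0.014 as the mean of probes, and interferon-stimulated genes (0.094) -0.040 with array weights. With the gland covariate neutrophil markers read 0.78, epithelial genes -0.16, high endothelial venule genes 0.12 and class II genes 0.0097; against wild-type replicate 2 alone neutrophil markers read 0.57 and high endothelial venule genes 0.022. With 1 array left out, cytokines ranged from -0.30 to 0.16, stromal markers from -0.26 to 0.15, interferon-stimulated genes from -0.15 to 0.31 and nerve genes from -0.12 to 0.030. The exocrine list has no value with its own mean as a covariate.

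Whether the replicate numbers pair the arrays stays open. The correlation of same-numbered arrays' deviations was 0.49, 0.32 and -0.31, and that of differently numbered arrays was not computed. With the replicate block 4685 probes were called (1854 higher, 2831 lower), and 14 lists, without that of V(D)J recombination (adjusted p = 0.056); of 99 named genes 90 kept their call. Of the 99, 92 to 98 kept direction and call under the background, offset and scaling alternatives and the authors' values, and 0 reversed under any setting. Leaving out 1 array kept between 50 and 95 of the calls, the gland covariate 66, no filter on dim probes 76, and wild-type replicate 2 alone 43. The covariate called 7 lists that were not called without it, among them cytokines with their sign turned, and ended the calls on the clock and V(D)J lists with no change of sign (adjusted p = 0.437 and 0.141). These covariate results rest largely on wild-type replicate 2. Signal over background limits the rest: 11319 probes were too dim to test.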

Other observations

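The tests of explanations in this part were all chosen after the results they bear on had been seen. The mean of 17 neutrophil markers was highest on wild-type replicates 1 and 3. It was 12.62 and 11 on these arrays, 8.37 on wild-type replicate 2, and 8.32, 8.55 and 9.95 on the knockout arrays. The mean on wild-type replicate 3 lay closer to that on knockout replicate 3 than to that on wild-type replicate 1. Not every marker followed this order. Camp read 11.4 on both knockout and wild-type replicate 3, and Il1r2 was highest on knockout replicate 3 (9.54), both named after their values were seen. Mpo, the myeloperoxidase of primary granules, read 13.79 and 12.59 on wild-type replicates 1 and 3, 7.89 on replicate 2 and 7.50, 7.16 and 10.35 on the knockout arrays. Elane and Ngp, like Mpo named after their values were seen, read 12.09 and 13.11 on wild-type replicate 1 and 10.76 and 10.61 on replicate 3. They read 6.58 and 7.38 on wild-type replicate 2 and 8.97 and 9.29 on knockout replicate 3. Mpo, Elane and Ngp did not pass the limma test between the genotypes. Of the 17 markers 0 rose and 1 fell (0 and 0 adjusted over the list alone). That gene, the chemokine receptor gene Cxcr2, fell by 1.90 (SE 0.42, limma adjusted p = 0.021), and its call was lost without knockout replicate 2 or 3 or wild-type replicate 3, at an adjusted p of up to 0.072. Camera called the list lower (adjusted p = 0.046, and adjusted p = 0.867 with an estimated correlation), but not without knockout replicate 1 (0.144) or 2 (0.087) or wild-type replicate 1 (0.276) or 3 (0.065). The mean change of the list, -1.73 on all arrays, lay between -2.87 and -0.75 with 1 array left out. Its sign turned with the gland covariate (0.78) and against wild-type replicate 2 alone (0.57). Without wild-type replicate 2, 13 of the markers were lower.

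Kallikreins of the Klk1b family differed between arrays of 1 group. The median of 10 family members was 7.73, 15.70 and 12.75 on the knockout arrays and 4.96, 8.0 and 5.03 on the wild-type arrays. Prol1, another secreted salivary gene, read 5.19 on knockout replicate 1 and 16.02 on knockout replicate 2. Among the exocrine genes, Amy1 read 11.12, 8.45 and 7.67 on the knockout arrays and 7.34, 8.42 and 8.5 on the wild-type arrays, unlike Dcpp1. Prol1 and Amy1 were chosen after their values were seen.

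The lists of salivary gland and epithelial genes were high on the knockout arrays and on wild-type replicate 2. On a scale where 0 is the mean of wild-type replicates 1 and 3 and 1 the knockout mean, wild-type replicate 2 lay at 0.916 for the exocrine list, and at 0.761 for the 6 members left without the 4 that read at least 15.67 on it and on each knockout array, near the highest signal of 16.04; the mean of the 6 was 3.06 above that on the higher of the other wild-type arrays, which differed by 0.17, and this argues against genotype as the whole cause. It lay at 0.145 for the B cell list and 0.129 for the T cell list, which argues against a mislabelled knockout. Salivary tissue carried along with the node is consistent with the position of 0.928 for the epithelial list, although 4 of the 10 exocrine and 9 of the 17 epithelial genes were also detected on wild-type replicate 1 or 3. A further effect of genotype on these genes stays open, also because differences near the top of the scale are compressed, as do uneven dissection and which node was taken.

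Genes around Rag2 included several whose groups lay over 1.5 apart on the log2 scale. Within 100 tested genes on either side there were 12, 9 lower and 3 higher in the knockout. Among them were Tmem87a, at least 26.8-fold higher, and its close neighbour Lrrc57, at least 17.4-fold lower, the latter chosen after its value was seen. Counted in tested genes from Rag2, Cdca7 lay at -90 and Kif18a at 24, both named after their values were seen. All others lay on the side of Kif18a, at 51 to 93. A chromosome segment carried along with the targeted allele could place strain variants there: 0.0353 of equally long runs of genes held as many, but 0.576 did for 25 genes and 0.823 for 50 genes to either side, so the test does not decide. Among the 9 lower genes was Nusap1 (-3.17), which also counts among the falling cell cycle genes, so the 2 patterns share this gene. A lower share of lymphocytes would raise other transcripts alike. The 3 that rose had a median of 2.88, above the 95th percentile of 1.87 among 119 markers of other cells, but they were picked for large gaps, so this too stays open, and variants under the probes were not tested.

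Of 8 called clock genes, 7 went in the direction of a single phase shift, with Nr1d1 (1.75, SE 0.49), Dbp, Per2, Per3, Cry2 and Tef up and Arntl down, and Nfil3 (1.43, SE 0.40) against it (exact two-sided binomial p = 0.0703, over genes that are not independent). A different clock phase at collection may account for this, but the test does not decide, and an effect of genotype or of the mix of cells was not tested. Against gland tissue as the whole cause, wild-type replicate 2 lay at 0.336 on the same scale for output genes minus Arntl and Clock, and 1.10 below the nearest knockout array, where the knockout range was 0.521, and Arntl (-1.47) and Tef (1.54) stayed called with the gland covariate. A part played by gland tissue stays open: wild-type replicate 2 lay at 0.594 for the mean of the clock list, and the covariate lowered that list's mean change from 0.654 to 0.275 (camera adjusted p = 0.437), Nr1d1 to 0.64 and Nfil3 to 0.70, both no longer called. The calls of Nr1d1 and Nfil3 were lost without knockout replicate 2 or 3 or wild-type replicate 1 or 3, and that of Nr1d1 without knockout replicate 1 (adjusted p up to 0.113 and 0.127).

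Among the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called probes as the real one (4119), which is the real split itself; the highest other count was 0. For called lists, 4 of the 10 splits, the real one included, gave at least the real 15, and the highest other gave 17. The lowest other split gave 8. Each other split puts arrays of both genotypes in each group. Its contrast keeps part of the genotype difference, which can call lists. The rest widens the spread within its groups, which works against called probes. The other splits thus show neither count under chance alone, and nothing is concluded from either comparison. With 10 splits a share under 0.05 cannot be reached.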
